A study of Mus musculus with 67 samples.

How the data were processed

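The series held 67 RNA sequencing libraries from mouse brain in 3 experiments, and each experiment was given as its own table. The deposited values were raw read counts per gene over exons, whole numbers with a different total in each library, and every library had a column of its own. The tables listed 24421 genes for the LPS experiment and 24411 genes for the others, identified by symbol. The submitters' processing notes named bcl2fastq, HISAT version 0.1.5, HOMER and the mouse genome build mm9, without saying which step each tool served. The annotation, the strand setting and the handling of duplicates or molecular identifiers were not given in the sources used here, and read alignments were not used.

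Per the labels, mice were C57BL/6J with the RiboTag allele and a Cre recombinase expressed from Cx3cr1. Tamoxifen was given to the groups labelled as treated, by gavage, as 4 doses of 5 mg from 4 to 6 weeks of age. Tagged ribosomes were pulled down from flash-frozen brain homogenate with an anti-HA antibody for 4 h, and a mouse IgG1 served as the control. The stated amounts were 125 µg of anti-HA and 1 µg of IgG1, so the control was not matched in the amount of antibody as stated. Sorted cells came from a fresh preparation with a Percoll gradient, with or without a 20 min digest in Collagenase D and DNase at 37 °C. The gate was GR1 negative, CD45 intermediate and CD11b positive. LPS was injected at 2.5 mg/kg and tissue was taken after 3 h.

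Libraries were grouped by experiment, treatment or genotype and preparation, with 2 to 4 libraries per group. The design text states that replicates were separate mice. The series text states that sorting and pull-down were done on the same animal, but not that the replicate number marks the animal, so the number was not used as a pair in the tests. A fit with the number as a block was run as an alternative. The comparisons, their tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from 3 alternatives and the tests and observations that the closing section names as chosen later.

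Each experiment was fitted with edgeR version 4.0.16 in R version 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, and library sizes were scaled by the trimmed mean of M values (TMM). Groups were compared with the edgeR quasi-likelihood F test with robust dispersions. The p values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Errors printed after a log2 fold change are standard errors (SE) from this fit. Expression is given as CPM, the TMM-scaled counts relative to a common library size, with the standard deviation (SD) between libraries. The fit left 11444 genes in the LPS experiment, 11529 in the digest experiment and 11868 in the driver experiment.

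Gene lists were tested with camera from limma version 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Lists with fewer than 5 tested members were described by counts alone. Camera was repeated with an estimated correlation, and fry served as another alternative. The 22 lists were microglia, perivascular and border macrophage, neutrophil and monocyte, lymphocyte, neuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, endothelial, pericyte and smooth muscle, ependymal and choroid plexus, erythroid, immediate early, heat shock, NF-kB and inflammatory cytokine, chemokine, interferon-stimulated, disease-associated microglia, ribosomal protein, oxidative phosphorylation, nuclear long noncoding and cell cycle. No tested gene stood in more than 1 list. For each list the members called are given over all genes tested and adjusted over the list alone. Where a list has a single count, both were equal. The first value in parentheses after a list is its adjusted camera p.

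Named genes were, per comparison, the 5 with the largest and the 5 with the smallest log2 fold change among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups. The condition on overlap was dropped for interaction terms. Symbols of predicted genes, microRNAs and small nucleolar RNAs were skipped. Added to these were the 3 members of each described list with the smallest p and a set of fixed genes, among them Tmem119, P2ry12, Cx3cr1, Mrc1, Fos, Tnf, Il1b, Snap25, Gfap and Cldn5. The text leaves some of them out, and some genes that met these rules are not reported here.

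A fold against a group with no read for a gene is a lower bound, computed against a floor of 3 reads over the group, and is written as "at least". Where a group held 1 to 3 reads, the ratio of depth-scaled reads is given with its exact 95% confidence interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Totals ran from 166851 to 3513317 counts per library, and 3 reads in a single library stood for up to 18 CPM in the shallowest group.

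Alternatives were DESeq2 size factors in edgeR, total-count scaling, the Wald test of DESeq2 version 1.42.0, no filter on low counts, a minimum count of 50, a fit on the groups of the contrast alone, the replicate block, and leaving out each library in turn. Group labels were also regrouped to count how many genes other splits of the libraries call. The workflow was tested on simulated data drawn at the depths of 4 comparisons, with 100 genes changed 2-fold and 100 changed 4-fold. The edgeR test recovered 61 and 88 of them in the pull-down LPS comparison, 64 and 83 in the digest comparison, 21 and 54 in the interaction between LPS and pull-down from sorted cells, and 9 and 53 in the comparison of pull-downs without and with tamoxifen. Genes called without a simulated change numbered 10 of 169, 7 of 167, 6 of 84 and 7 of 70 calls in that order, or 5.92%, 4.19%, 7.14% and 10%. A changed list was found in each of the 4, and 0 of 20 unchanged lists per comparison had an unadjusted camera p under 0.05. Simulated genes were drawn independently of each other, so false list calls from correlation between genes could not show. Far fewer genes were changed than most comparisons of pull-down or sorted cells called, so false calls under such wide change were not measured. Figures were drawn with matplotlib version 3.10.9. Isoforms, introns and single reads were not analysed here.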

Results

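Gene expression was measured by RNA sequencing in 67 libraries from mouse brain, in 3 experiments that set ribosome-bound RNA pulled down from whole brain beside RNA of sorted microglia. In the RiboTag design, Cre recombinase expressed from the Cx3cr1 locus tags the ribosomal protein Rpl22 with HA in cells that recombine, and an anti-HA antibody pulls the tagged ribosomes and their RNA out of a homogenate. Pull-down with an IgG1 antibody gave the background. Replicates were separate mice per the design text, and values after ± are standard errors of a log2 fold change unless SD is named.

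The driver experiment compared 3 kinds of mice, each with pull-down, IgG1 and input libraries. These were the inducible driver CX3CR1CreER with tamoxifen (3 mice), the same driver without tamoxifen (2 mice) and the constitutive driver CX3CR1Cre (3 mice). The digest experiment held pull-down (3), IgG1 (4), cells sorted after an enzymatic digest (4) and cells sorted without it (4). In the LPS experiment, mice received PBS (3) or lipopolysaccharide (LPS, 4), a bacterial product that triggers inflammation, and each treatment had pull-down, IgG1, sorted and pull-down from sorted cells. Total counts per library ran from 1131402 to 3513317 in pull-downs of the LPS experiment, 610257 to 1183677 in IgG1, 501321 to 1020518 in sorted cells and 166851 to 669508 in pull-downs from sorted cells. In the digest experiment they ran from 685218 to 1843618. In the driver experiment, input held 1285195 to 2084562 counts, IgG1 449396 to 1215785, pull-down with tamoxifen 918587 to 1152419, pull-down with the constitutive driver 1297297 to 1772469 and pull-down without tamoxifen 186099 to 219521.

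The first question was which RNA the pull-down enriched with the inducible driver after tamoxifen. Microglial genes were far higher in pull-down than in input (n = 3 each). Tmem119, a microglial surface marker, stood at 4740 ± 513 CPM (SD) against 39.5 ± 6.09 CPM, a log2 difference of 6.91 ± 0.38. The fractalkine receptor Cx3cr1 was higher by 5.44 ± 0.41 and the purinergic receptor P2ry12 by 3.80 ± 0.33. C5ar2, a complement receptor, had 51 reads in pull-down and 0 in input and was at least 35.9-fold higher. Genes of other brain cells were lower, among them the synaptic gene Snap25 (-3.03 ± 0.20) and the water channel Aqp4 of astrocytes (-4.99 ± 0.53). Ugt8a, an enzyme of myelin lipid synthesis, had 124 reads in input and 0 in pull-down and was at least 19.6-fold lower.

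By list, 23 of 23 microglial genes were higher, with a median of 6.12 (adjusted camera p = 2.83e-34, adjusted p = 0.00475 with an estimated correlation). The perivascular and border macrophage list was higher in 11 of 11, with a median of 5.14 (6.1e-12, adjusted p = 0.00475 with an estimated correlation), including Pf4 (5.92 ± 0.32) and Mrc1 (4.44 ± 0.66). Disease-associated microglia genes, many of them lysosomal, were higher in 16 and lower in 2 of 20 (5.04e-08, adjusted p = 0.0161 with an estimated correlation). Of 16 NF-kB and inflammatory cytokine genes 12 were higher and 1 lower (6.42e-07, adjusted p = 0.00475 with an estimated correlation), with the LPS co-receptor Cd14 at 5.87 ± 0.35. Interferon-stimulated genes were higher in 19 and lower in 1 of 21 (1.97e-05, adjusted p = 0.0226 with an estimated correlation). Chemokines were higher in 8 of 9 (0.000888, adjusted p = 0.105 with an estimated correlation). Neuronal genes were lower in 21 of 23, with a median of -1.38 (3.57e-08, adjusted p = 0.00475 with an estimated correlation).

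Other glial lists moved down with the neuronal one. Astrocyte genes were lower in 13 of 15 (0.00148, adjusted p = 0.517 with an estimated correlation), and oligodendrocyte genes in 12 of 15 with 1 higher (0.0127, adjusted p = 0.614 with an estimated correlation). The 1 higher was the iron carrier Trf (2.43 ± 0.25). The 5 nuclear long noncoding RNAs, which are not translated, were all lower, with a median of -2.87 (0.0295, adjusted p = 0.149 with an estimated correlation). Ribosomal protein genes were higher in 44 and lower in 3 of 70, with a median of 1.00 (1.54e-05, adjusted p = 0.517 with an estimated correlation). Of 82 oxidative phosphorylation genes 10 were higher and 35 lower, or 9 and 35 adjusted over the list alone (0.0388, adjusted p = 0.649 with an estimated correlation).

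The remaining lists did not pass camera. Members lower were 4 of 9 for oligodendrocyte precursors (0.312), 2 of 6 for pericytes and smooth muscle (0.312, 1 adjusted over the list alone), 4 of 7 for ependyma and choroid plexus (0.312) and 2 of 6 for erythroid genes (0.541, 0 adjusted over the list alone). Of 11 endothelial genes 1 was higher and 2 lower (0.489), of 24 immediate early genes 7 higher and 9 lower (0.559), and of 12 heat shock genes 4 higher and 2 lower (0.882). For heat shock the median was 0.09, the mean -0.06 and the direction of the test down. Lists too small for camera held Mmp9 (5.75 ± 0.36) and S100a9 (not called, 16 reads in input against 2, a ratio of 3.79 with a 95% interval of 0.89 to 33.9) for neutrophils and monocytes, the B cell gene Cd79b (5.18 ± 0.50) for lymphocytes, and Mcm5 (1.86 ± 0.41), Mcm2 (1.83 ± 0.54) and Pcna (-1.25 ± 0.27) for the cell cycle. The edgeR test called 7617 of 11868 genes, 3402 higher and 4215 lower. With total-count scaling 28.8% of called genes were higher and with the DESeq2 Wald test 50.6%, against 44.7%.

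Against IgG1, the background of the pull-down, microglial genes were again higher. Tmem119 was higher in pull-down by 6.18 ± 0.36 (n = 3 each). Arl11 and the sialic acid receptor Cd33 had 251 and 237 reads in pull-down and 0 in IgG1, at least 126-fold and 119-fold higher. In the microglial list, genes were higher in 23 of 23, with a median of 6.21 (adjusted camera p = 7.35e-31, adjusted p = 0.00479 with an estimated correlation), and border macrophage genes in 11 of 11, with a median of 5.82, or 5.49 with 2 genes at their bound. Neuronal genes were lower in 22 of 23, or 23 adjusted over the list alone, with a median of -2.00 (1.71e-10, adjusted p = 0.00479 with an estimated correlation). By the edgeR test 7850 genes were called, 3659 higher and 4191 lower. Total-count scaling gave 30.4% higher against 46.6%, and it moved the median gene by -0.53, the largest shift of any scaling in these comparisons.

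The constitutive driver raised the question whether the same enrichment was seen without tamoxifen induction. Microglial genes were higher in pull-down than in input here too, by less (n = 3 each). Tmem119 was higher by 2.87 ± 0.33 and the complement gene C1qa by 2.50 ± 0.27, while P2ry12 did not pass (0.67 ± 0.40, adjusted p = 0.193). Parvalbumin (Pvalb), a calcium buffer of interneurons, was higher by 1.87 ± 0.21, and the neuronal genes Calb1 (-1.31 ± 0.19) and Map2 (-1.14 ± 0.19) were lower. Among the long noncoding RNAs, Meg3 fell by 3.53 ± 0.52 and Neat1 by 2.56 ± 0.37.

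Of 23 microglial genes 19 were higher and 0 lower, or 19 and 1 adjusted over the list alone, with a median of 2.08 (adjusted camera p = 1.39e-15, adjusted p = 0.0842 with an estimated correlation). The neuronal list held 11 higher and 5 lower members (0.211). Oxidative phosphorylation genes were higher in 56 of 82, or 58 adjusted over the list alone (1.51e-21, adjusted p = 0.0832 with an estimated correlation). Nuclear long noncoding RNAs were lower in 5 of 5 (4.72e-05, adjusted p = 0.0416 with an estimated correlation). In total 4138 genes passed, 2144 higher and 1994 lower, with 51.8% higher against 28.1% with total-count scaling. Pull-down replicate 1 stood apart from the others in markers of other cells. Its mean log2 CPM was 7.42 for astrocyte genes against 5.75 and 5.72, 4.18 for endothelial genes against 2.47 and 2.25, and 6.15 for microglial genes against 7.08 and 7.19. Without it 4017 genes were called.

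**Figure D1:**
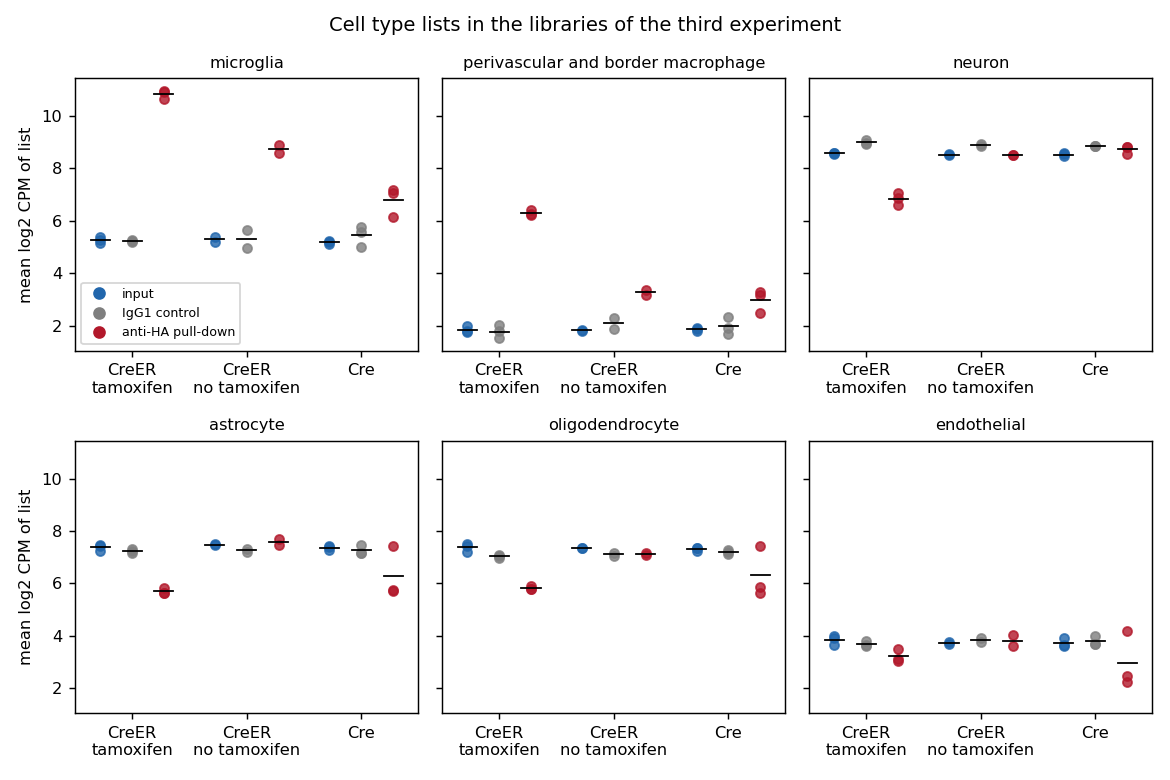
Mean log2 CPM of 6 cell type lists in each library of the driver experiment. Points are libraries (input blue, IgG1 grey, pull-down red), black lines are group means, and pull-down replicate 1 of the constitutive driver lies at 7.42 in the astrocyte list, above the other pull-downs of its group at 5.75 and 5.72.

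Pull-downs of both drivers were then compared with each other. With the constitutive driver, neuronal genes were higher and microglial genes lower (n = 3 each). Snap25 was higher by 2.78 ± 0.20 and Stmn2, a neuronal growth protein, by 2.57 ± 0.17. Tmem119 fell by 4.43 ± 0.33, from 4740 ± 513 to 221 ± 99.3 CPM (SD), and the transcription factor Sall1 fell by 4.27 ± 0.27. Microglial genes were lower in 23 of 23, with a median of -4.14 (adjusted camera p = 1.17e-28, adjusted p = 0.00281 with an estimated correlation), and neuronal genes were higher in 23 of 23, with a median of 1.75 (1.35e-12, adjusted p = 0.00281 with an estimated correlation). Oxidative phosphorylation genes were higher in 72 of 82, or 74 adjusted over the list alone (3.71e-14, adjusted p = 0.0795 with an estimated correlation). Astrocyte genes, raised in replicate 1 of the constitutive driver, were higher in 6 of 15 (0.188). In all, 6616 genes passed the edgeR test, 3579 higher and 3037 lower, or 54.1% higher against 46.5% with DESeq2 size factors and 45.6% with the DESeq2 Wald test.

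The difference between drivers held when each pull-down was taken relative to its own input, as an interaction term. There, Snap25 was higher by 2.78 ± 0.27 and the synaptic calcium sensor Syt1 by 3.43 ± 0.32, while Csf1r, the receptor on which microglia depend, fell by 4.92 ± 0.38 and Runx1, a transcription factor of blood and myeloid cells, by 6.66 ± 0.83. Neuronal genes were higher in 22 of 23, or 23 adjusted over the list alone (adjusted camera p = 8.49e-14, adjusted p = 0.00281 with an estimated correlation), and microglial genes lower in 22 of 23 (4.92e-31, adjusted p = 0.00618 with an estimated correlation). The term was called for 5171 genes, 2838 higher and 2333 lower. The majority turned with scaling, from 54.9% higher to 46.2% with DESeq2 size factors and 45.3% with the DESeq2 Wald test, and was 64.2% with total-count scaling. Between the inputs of both drivers, edgeR called 0 genes, or 1 without input replicate 3 of the mice with tamoxifen, with 507 at an unadjusted p under 0.05, but lists differed. With the constitutive driver, immediate early genes were lower in input as a list, with a median of -0.44 (adjusted camera p = 5.68e-10, adjusted p = 0.0498 with an estimated correlation). Their median was -0.25 without that library (1.52e-05, adjusted p = 0.18 with an estimated correlation). Erythroid genes had a median of -1.18 (8.2e-07, adjusted p = 0.225 with an estimated correlation), which rested on input replicate 2 with tamoxifen and was -0.38 without it (0.148). Heat shock genes (0.00874, adjusted p = 0.225 with an estimated correlation) and ribosomal protein genes (0.000269, adjusted p = 0.955 with an estimated correlation) also lost the call with 1 library left out, at up to 0.233 and 0.148. The immediate early gene Fos stood at 52.6 ± 7.99 CPM (SD) in these inputs and 97.5 ± 11.3 CPM in inputs with tamoxifen, which enters its term of 1.82.

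Mice with the inducible driver and no tamoxifen served as a control of the induction. Their pull-down still held microglial RNA, at n = 2 and the lowest depth of the experiment. Tmem119 stood at 697 ± 135 CPM (SD) in pull-down and 32.8 ± 8.04 CPM in input, a log2 difference of 4.41 ± 0.44. Cx3cr1 was higher by 5.56 ± 0.59, P2ry12 by 4.28 ± 0.45 and Csf1r by 4.24 ± 0.35. The matrix metalloproteinases Mmp2 and Mmp9 were high, at 912 ± 3.96 and 526 ± 12.3 CPM, and Mmp2 had a ratio of 928 to input (95% interval 315 to 4520). In the digest experiment, both were also higher in pull-down than in IgG1, by 5.70 and 6.02.

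Microglial genes were higher in 22 of 23, with a median of 3.74 (adjusted camera p = 1.24e-76, adjusted p = 0.000153 with an estimated correlation). Border macrophage genes were higher in 4 of 11, or 7 adjusted over the list alone (0.000257, adjusted p = 0.066 with an estimated correlation). The neuronal list held 1 higher and 1 lower member of 23 (0.989), with a median of 0.06 and a mean of 0.00 with the test down. Across all genes tested, 1293 genes were called, 764 higher and 529 lower, and the DESeq2 Wald test gave 69.8% higher against 59.1%. Each of the 4 libraries decided the count. It was 451 without pull-down replicate 1, 673 without pull-down replicate 2, 765 without input replicate 1 and 817 without input replicate 2, with the lone library assumed to vary like the other groups. Against IgG1 of the same mice, 965 genes were called, 359 without pull-down replicate 1 and 496 without replicate 2, and microglial genes were higher in 22 of 23, with a median of 3.63 (5.82e-82, adjusted p = 7.65e-05 with an estimated correlation).

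Relative to pull-down with tamoxifen, most microglial genes were lower without it (n = 2 and 3). Tmem119 fell by 2.76 ± 0.37 and the integrin Itgam by 3.31 ± 0.32, while P2ry12 did not pass (0.11 ± 0.34, adjusted p = 0.834). Mmp9 was higher by 2.23 ± 0.26, Snap25 by 2.33 ± 0.22 and the neuronal calcium buffer Calb1 by 4.56 ± 0.32. Microglial genes were lower in 21 and higher in 1 of 23, with a median of -2.63 (adjusted camera p = 1.24e-17, adjusted p = 0.0421 with an estimated correlation), and neuronal genes higher in 21 of 23 (1.25e-17, adjusted p = 0.000657 with an estimated correlation). Ribosomal protein genes were lower in 38 and higher in 3 of 70, or 39 and 3 adjusted over the list alone (7.79e-09, adjusted p = 0.281 with an estimated correlation). The edgeR test called 4120 genes, 1944 higher and 2176 lower, with 47.2% higher against 70.3% with total-count scaling. Without pull-down replicate 1 of the mice without tamoxifen the count was 2517.

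The digest experiment asked how enrichment by pull-down compared with sorting, and what the enzymatic digest added. Pull-down was first set against IgG1 (n = 3 and 4). Tmem119 was higher by 6.05 ± 0.15, the lysosomal gene Laptm5 by 6.63 ± 0.14 and P2ry12 by 4.49 ± 0.20. Folr2, a folate receptor of border macrophages, had 334 reads against 0 and was at least 125-fold higher. Snap25 fell by 2.33 ± 0.17, from 948 ± 190 to 189 ± 21.7 CPM (SD), and Gfap, the filament of astrocytes, fell by 3.13 ± 0.22. In the microglial list, genes were higher in 24 of 24, with a median of 5.69 (adjusted camera p = 7.52e-39, adjusted p = 0.0034 with an estimated correlation), border macrophage genes in 11 of 11 (5.48e-11, adjusted p = 0.00868 with an estimated correlation), and neuronal genes lower in 23 of 23 (6.51e-10, adjusted p = 0.00868 with an estimated correlation). By the edgeR test 8594 of 11529 genes were called, 3078 higher and 5516 lower, or 35.8% higher against 48.1% in a fit on these groups alone, which moved the median gene from -0.47 to -0.09.

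Cells sorted after the digest differed from pull-down in markers of activation and of other cells (n = 4 and 3). Fos, an immediate early transcription factor, stood at 2560 ± 460 CPM (SD) in sorted cells and 19.9 ± 3.83 in pull-down, a log2 difference of 7.01 ± 0.22. Tnf, an inflammatory cytokine, had 778 reads against 3, a ratio of 253 (95% interval 86.1 to 1230). Mrc1 fell by 3.40 ± 0.37 and the platelet factor Pf4 by 8.10 ± 0.33. Snap25 had 2 reads against 851 in pull-down, a ratio of 437 (121 to 3610), and Mmp17 had 0 against 1223 and was at least 419-fold lower. Tmem119 did not pass (0.06 ± 0.12, adjusted p = 0.664), while P2ry12 was higher by 4.17 ± 0.16.

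Immediate early genes were higher in 21 and lower in 2 of 24, with a median of 4.41 (adjusted camera p = 6.8e-23, adjusted p = 0.0138 with an estimated correlation). NF-kB and inflammatory cytokine genes were higher in 14 and lower in 2 of 22 (1.5e-06, adjusted p = 0.0162 with an estimated correlation). Microglial genes were higher in 12 and lower in 5 of 24 (0.000644, adjusted p = 0.199 with an estimated correlation). Border macrophage genes were lower in 10 of 11, with a median of -6.35 (2.14e-09, adjusted p = 0.00105 with an estimated correlation), and neuronal genes in 23 of 23, with a median of -7.26, or -7.14 with 6 genes at their bound (3.24e-21, adjusted p = 0.000187 with an estimated correlation). Astrocyte genes were lower in 14 and higher in 1 of 15 (5.21e-08, adjusted p = 0.0235 with an estimated correlation). Nuclear long noncoding RNAs were higher in 5 and lower in 2 of 8 (0.000612, adjusted p = 0.0486 with an estimated correlation), with Neat1 at 5.67 ± 0.25. In total 8391 genes passed, 3647 higher and 4744 lower.

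Sorting without the digest gave a similar picture against pull-down (n = 4 and 3). Fos was higher by 6.56 ± 0.22, Jun, its partner in the AP-1 factor, by 5.20 ± 0.17, and the chemokine Ccl2 by 6.16 ± 0.29. Pf4 fell by 6.24 ± 0.26, and the neuronal elongation factor Eef1a2 had 0 reads against 1441 and was at least 533-fold lower. Immediate early genes were higher in 19 and lower in 2 of 24 (adjusted camera p = 2.06e-19, adjusted p = 0.0231 with an estimated correlation). Neuronal genes were lower in 23 of 23, with a median of -8.05, or -7.28 with 8 genes at their bound (9.12e-22, adjusted p = 0.000344 with an estimated correlation), and border macrophage genes in 10 of 11 (7.08e-09, adjusted p = 0.000521 with an estimated correlation). In all, 8397 genes passed the edgeR test, 3679 higher and 4718 lower, or 43.8% higher against 51.2% with total-count scaling.

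The digest itself changed few genes (n = 4 each). With it, Gadd45b, a stress-response gene, was higher by 1.58 ± 0.18, the chemokine receptor-like Ccrl2 by 1.5 ± 0.15, the NF-kB regulator Nfkbiz by 1.21 ± 0.15 and the chemokine Ccl4 by 1.09 ± 0.13, while Ccl2 fell by 0.95 ± 0.16. Fos did not pass (0.45 ± 0.14, adjusted p = 0.51). Of 24 immediate early genes 2 were higher, or 9 higher and 2 lower adjusted over the list alone (adjusted camera p = 2.51e-18, adjusted p = 0.0207 with an estimated correlation). NF-kB and inflammatory cytokine genes were higher in 2 of 22, or 5 adjusted over the list alone (2.38e-07, adjusted p = 0.02 with an estimated correlation). No ribosomal protein gene of 67 passed over all genes, and 7 were higher adjusted over the list alone (3.69e-16, adjusted p = 0.0207 with an estimated correlation), with a median of 0.26. Heat shock genes gave 0 and 2 of 12 (0.00128, adjusted p = 0.219 with an estimated correlation). In the border macrophage list 0 of 11 passed, with a median of -1.15 (0.00067, adjusted p = 0.02 with an estimated correlation). Across all genes tested, 16 genes were called, 14 higher and 2 lower, and 521 had an unadjusted p under 0.05.

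**Figure D2:**
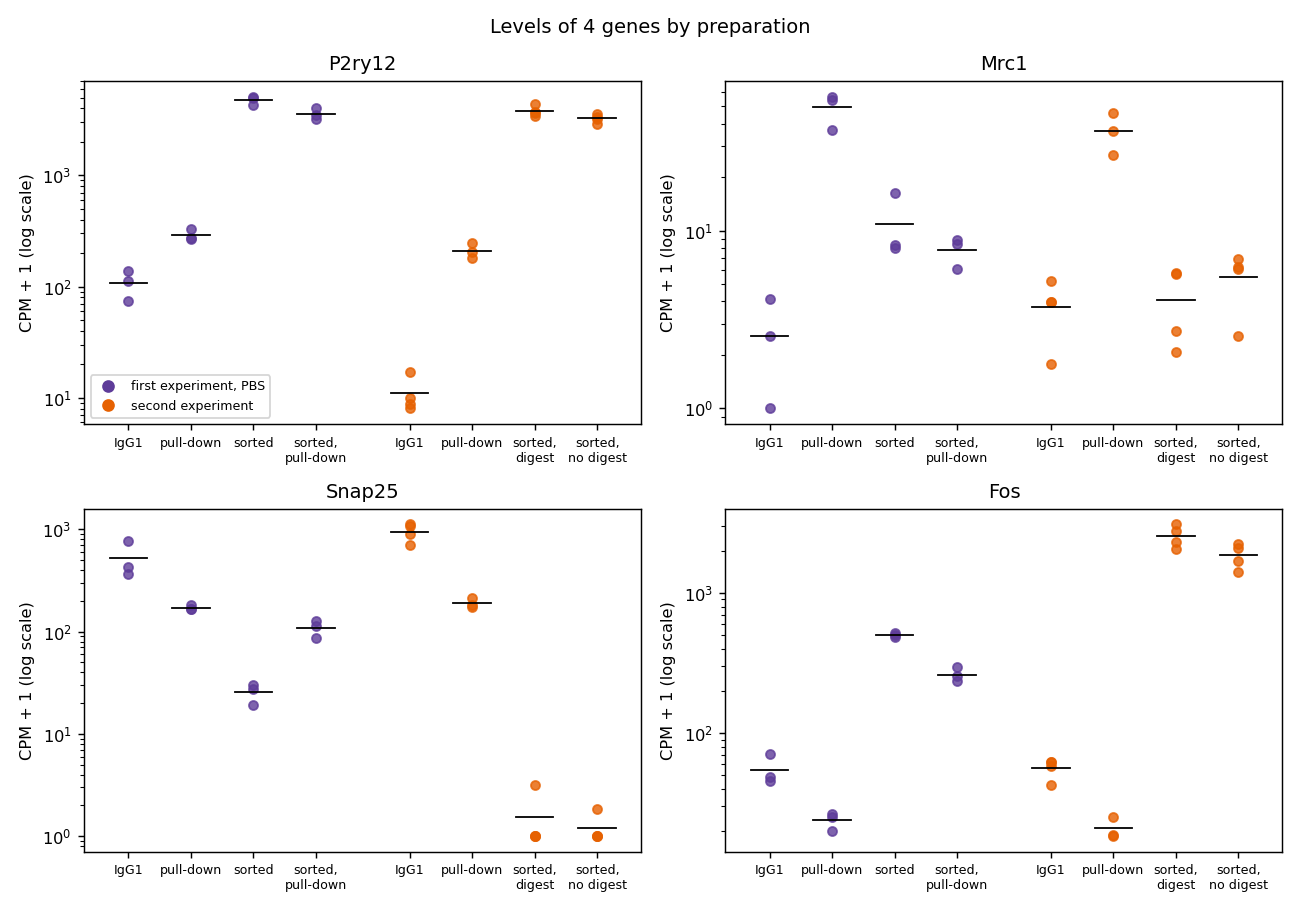
CPM plus 1 on a log axis of P2ry12, Mrc1, Snap25 and Fos in each library of the preparations, for PBS mice of the LPS experiment and for the digest experiment. Points are libraries and black lines are group means, with mean Fos at 19.9 CPM in pull-down and 2560 CPM in cells sorted after the digest.

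The LPS experiment repeated the comparison of preparations in PBS mice (n = 3 each). Against IgG1, pull-down was higher for Tmem119 by 5.94 ± 0.26, Olfml3 by 6.13 ± 0.23 and Pf4 by 6.83 ± 0.29, and for P2ry12 by 1.42 ± 0.21. The kinase gene Camk2a of neurons fell by 2.05 ± 0.19. In the microglial list, genes were higher in 24 of 24, with a median of 4.70 (adjusted camera p = 1.5e-41, adjusted p = 0.000787 with an estimated correlation), border macrophage genes in 11 of 11 (9.12e-11, adjusted p = 0.00319 with an estimated correlation), and ribosomal protein genes in 61 of 74 with 1 lower (5.85e-10, adjusted p = 0.0407 with an estimated correlation). Neuronal genes were lower in 23 of 23 (8.21e-07, adjusted p = 0.167 with an estimated correlation). The edgeR test called 7434 of 11444 genes, 3776 higher and 3658 lower. The share higher was 50.8%, against 32.2% with DESeq2 size factors, 35.2% with total-count scaling and 32.1% with the DESeq2 Wald test.

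Sorted cells of PBS mice differed from pull-down as in the digest experiment (n = 3 each). Fos was higher by 4.43 ± 0.26, at 500 ± 14.5 CPM (SD) against 23.0 ± 3.42, and Jun by 3.93 ± 0.18. P2ry12 was higher by 4.04 ± 0.21 and the receptor Gpr34 by 4.67 ± 0.22, while Tmem119 did not pass (-0.28 ± 0.20, adjusted p = 0.214). The scavenger receptor Cd163 of border macrophages had 0 reads against 497 and was at least 99.7-fold lower. Immediate early genes were higher in 15 and lower in 6 of 24 (adjusted camera p = 5.01e-05, adjusted p = 0.0466 with an estimated correlation). Border macrophage genes were lower in 10 of 11, with a median of -5.96, or -5.22 with 4 genes at their bound (2.38e-06, adjusted p = 0.0391 with an estimated correlation), and neuronal genes in 23 of 23 (5.9e-12, adjusted p = 0.0572 with an estimated correlation). Oxidative phosphorylation genes were lower in 60 and higher in 7 of 80 (8.78e-08, adjusted p = 0.0391 with an estimated correlation). By the edgeR test 8226 genes were called, 3798 higher and 4428 lower, or 46.2% higher against 32.2% with no filter on low counts and 52.4% with total-count scaling.

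Both experiments were set side by side for this comparison over 10930 genes. Called in the same direction were 6760 genes, 2990 higher and 3770 lower, where 1147 and 1784 would be met by independent draws. In opposite directions were 37. Sorted cells held Xist reads in the digest experiment and Ddx3y reads in the LPS experiment, so the animals differed in sex-linked RNA. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.92 and Spearman's rho 0.94.

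Pull-down from sorted cells was compared with sorted cells to see what the pull-down step changed in the same cell population (PBS, n = 3 each). The complement gene C1qc was higher by 1.67 ± 0.20 and Apoe, a lipid carrier, by 1.36 ± 0.22. Neurogranin (Nrgn), a postsynaptic gene, was higher by 3.31 ± 0.28. Egr1 fell by 1.99 ± 0.22, Jun by 1.38 ± 0.17, and the noncoding RNAs Malat1 by 2.50 ± 0.24 and Kcnq1ot1 by 3.96 ± 0.38. The transcription factor Zbed6 had 103 reads in sorted cells and 0 after pull-down and was at least 18.7-fold lower. Neuronal genes were higher in 15 of 23, or 17 adjusted over the list alone (adjusted camera p = 1.29e-09, adjusted p = 0.176 with an estimated correlation), and astrocyte genes in 7 of 15, or 8 adjusted over the list alone (0.000204, adjusted p = 0.176 with an estimated correlation). Nuclear long noncoding RNAs were lower in 4 of 7, or 4 with 1 higher adjusted over the list alone (0.00032, adjusted p = 0.105 with an estimated correlation). Microglial genes were higher in 13 and lower in 5 of 24, or 14 and 7 adjusted over the list alone (0.00148, adjusted p = 0.392 with an estimated correlation). In total 3645 genes passed, 1905 higher and 1740 lower, with 52.3% higher against 31.5% with total-count scaling, 65% with no filter on low counts and 60.5% with the DESeq2 Wald test.

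Against pull-down from whole brain, pull-down from sorted cells kept the marks of sorting (PBS, n = 3 each). Fos was higher by 3.5 ± 0.27, Zfp36, a regulator of cytokine messages, by 4.38 ± 0.22, and P2ry12 by 3.62 ± 0.21. Mmp9 had 0 reads against 454 and was at least 49.5-fold lower, Pf4 fell by 6.41 ± 0.34, and the neuronal enolase Eno2 fell by 2.66 ± 0.22. Immediate early genes were higher in 14 and lower in 3 of 24, or 14 and 4 adjusted over the list alone (adjusted camera p = 2.51e-06, adjusted p = 0.0216 with an estimated correlation). In the microglial list, genes were higher in 20 and lower in 1 of 24, or 21 and 1 adjusted over the list alone (6.68e-14, adjusted p = 0.035 with an estimated correlation). Border macrophage genes were lower in 10 of 11 (4.45e-09, adjusted p = 0.0202 with an estimated correlation) and neuronal genes in 18 of 23, or 19 adjusted over the list alone (1.38e-09, adjusted p = 0.0669 with an estimated correlation). In all, 6145 genes passed the edgeR test, 2825 higher and 3320 lower, or 46% higher against 30.2% with no filter on low counts and 50.9% without the 3 shallowest libraries.

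The response to LPS was then measured in each preparation (LPS n = 4, PBS n = 3). In pull-down, the acute-phase gene Saa3 rose by 7.99 ± 0.57, from 9.25 ± 3.87 to 2350 ± 348 CPM (SD), the iron-binding Lcn2 rose by 6.46 ± 0.45, the cytokine Il1b by 4.89 ± 0.39 and Tnf by 4.69 ± 0.57. Socs3, a brake on cytokine signalling, rose by 5.92 ± 0.23. Gpr34 fell by 3.73 ± 0.32, P2ry12 by 2.03 ± 0.19 and Cx3cr1 by 1.79 ± 0.16. After LPS, P2ry12 stood at 54.3 to 99.4 CPM in pull-down and 79.4 to 111 CPM in IgG1, so it was not above background. Gpr34 was only 0.8 over IgG1 in PBS mice, on the log2 scale. Pull-down was not tested against IgG1 in LPS mice, so the falls of P2ry12 and Gpr34 may include background. Markers of other cells moved too. Gfap rose by 1.71 ± 0.30 and the endothelial junction gene Cldn5 fell by 2.26 ± 0.40.

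With LPS, NF-kB and inflammatory cytokine genes rose in 27 of 29, with a median of 3.32 (adjusted camera p = 3.04e-58, adjusted p = 7.33e-05 with an estimated correlation), and chemokines in 13 of 13 (5.19e-23, adjusted p = 0.000373 with an estimated correlation). Interferon-stimulated genes rose in 27 of 30, or 28 adjusted over the list alone (1.21e-30, adjusted p = 0.000103 with an estimated correlation). Immediate early genes rose in 14 and fell in 2 of 24, or 14 and 3 adjusted over the list alone (6.75e-13, adjusted p = 0.000323 with an estimated correlation). Microglial genes fell in 11 and rose in 1 of 24, or 12 and 1 adjusted over the list alone (4.61e-07, adjusted p = 0.213 with an estimated correlation). Across all genes tested, 3037 genes were called, 1779 higher and 1258 lower. The share higher was 58.6%, against 45% with DESeq2 size factors, 40.6% with total-count scaling and 46.2% with the DESeq2 Wald test.

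In sorted cells Il1b rose by 5.52 ± 0.36, Tnf by 4.00 ± 0.38 and Hcar2, a metabolite receptor, by 6.11 ± 0.42. Il1rn, the antagonist of interleukin 1, had 371 reads against 2, a ratio of 161 (95% interval 44.4 to 1340). Gpr34 fell by 2.93 ± 0.18, P2ry12 by 1.86 ± 0.18 and Tmem119 by 1.06 ± 0.19. The NF-kB and inflammatory cytokine list rose in 28 of 29, with a median of 3.01, or 2.98 with 1 gene at its bound (adjusted camera p = 7.47e-40, adjusted p = 0.000785 with an estimated correlation), chemokines in 13 of 13 (1.32e-16, adjusted p = 0.00377 with an estimated correlation) and interferon-stimulated genes in 23 of 30, or 28 adjusted over the list alone (1.69e-13, adjusted p = 0.00377 with an estimated correlation). Heat shock genes rose in 8 of 12 (0.0187, adjusted p = 0.545 with an estimated correlation). Microglial genes fell in 14 and rose in 2 of 24 (5.58e-08, adjusted p = 0.158 with an estimated correlation). The edgeR test called 3949 genes, 1940 higher and 2009 lower.

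Pull-down from sorted cells was measured at a lower depth. Il1b rose by 5.11 ± 0.39, Tnf by 4.92 ± 0.52 and the secreted phosphoprotein Spp1 by 6.21 ± 0.50. Sphk1, a lipid kinase, had 81 reads against 0 and was at least 25.5-fold higher. Gpr34 fell by 3.33 ± 0.21 and P2ry12 by 2.14 ± 0.18. NF-kB and inflammatory cytokine genes rose in 25 of 29 (adjusted camera p = 1.94e-47, adjusted p = 0.000326 with an estimated correlation), chemokines in 11 of 13, or 12 adjusted over the list alone (6.3e-20, adjusted p = 0.0013 with an estimated correlation), and interferon-stimulated genes in 25 of 30, or 26 adjusted over the list alone (1.82e-13, adjusted p = 0.00558 with an estimated correlation). Microglial genes fell in 17 of 24, or 18 adjusted over the list alone (1.42e-15, adjusted p = 0.0134 with an estimated correlation). By the edgeR test 2933 genes were called, 1458 higher and 1475 lower.

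The IgG1 libraries carried an LPS response of their own. The growth factor Csf3 rose by 4.99 ± 0.62, the antiviral gene Rsad2 by 4.16 ± 0.39 and Saa3 by 3.95 ± 0.65, to 87.1 ± 33.7 CPM (SD), and Cldn5 fell by 2.36 ± 0.35. Interferon-stimulated genes rose in 20 of 30, or 26 adjusted over the list alone (adjusted camera p = 3.65e-63, adjusted p = 3.69e-07 with an estimated correlation). The NF-kB and inflammatory cytokine list rose in 11 of 29, or 20 adjusted over the list alone (3.33e-42, adjusted p = 0.00022 with an estimated correlation), and chemokines in 6 of 13, or 12 adjusted over the list alone (2.56e-25, adjusted p = 0.000331 with an estimated correlation). Endothelial genes fell in 1 of 6, or 2 adjusted over the list alone (0.0016, adjusted p = 0.0314 with an estimated correlation). Of 24 microglial genes 0 passed (0.88). In total 132 genes passed, 115 higher and 17 lower, and 86 without LPS IgG1 replicate 2.

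**Figure D3:**
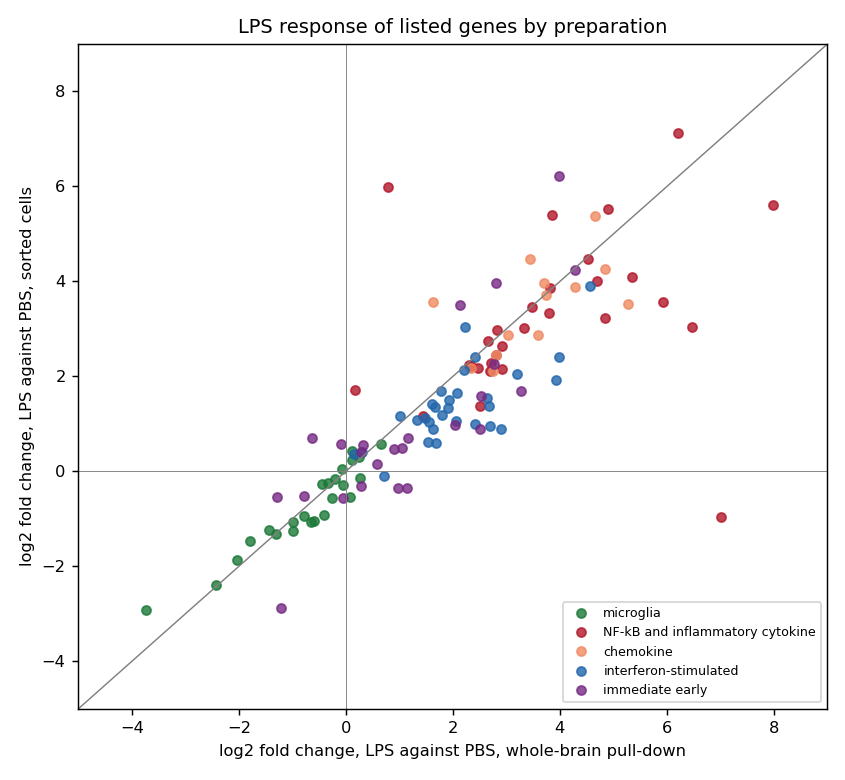
Log2 fold change of LPS over PBS in pull-down (horizontal) and in sorted cells (vertical) for the genes of 5 lists, with the identity line. NF-kB and inflammatory cytokine genes have medians of 3.32 and 3.01 on these axes.

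Pull-down and sorted cells shared 2151 LPS genes called in the same direction, 1257 higher and 894 lower, where 302 and 221 would be met by independent draws, and 17 were called in opposite directions. Sorted cells and pull-down from sorted cells shared 2318, with 0 opposite, and both pull-downs shared 1775, with 18 opposite. IgG1 shared 106 of its 132 genes with pull-down, 1 being opposite. Pearson's r across genes, which are not independent replicates, was 0.62, 0.59, 0.57 and 0.40 in this order. Sorting and pull-down were done on the same animal per the series text, so these overlaps are not a replication in separate mice.

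The interaction of LPS with preparation tested where the response differed between sorted cells and pull-down. Noct, a circadian phosphatase, responded more in sorted cells (5.28 ± 0.86, a fitted value with 1 read in sorted cells of PBS mice), and Socs3 (-2.36 ± 0.28), Jun (-1.48 ± 0.22), Zfp36 (-1.61 ± 0.26) and the interferon-stimulated Ifit3 (-1.98 ± 0.35) responded more in pull-down. Of these, Jun and Zfp36 were already high in sorted cells of PBS mice, with 3171 and 1539 reads against 346 and 135 in pull-down. With LPS they held 2903 and 3344 reads in sorted cells and 1296 and 1315 in the deeper pull-down. Their smaller fold in sorted cells was thus not a lower level. Without LPS, Socs3 had 323 reads in sorted cells against 82 in pull-down, and Ifit3 had 76 against 130. These reads are not scaled for depth. Libraries of PBS mice held 668194 to 1020518 counts in sorted cells and 1425412 to 1636479 in pull-down. The Ifit3 reads are thus no sign of a lower level in sorted cells. P2ry12 (0.17 ± 0.26, adjusted p = 0.828) and Il1b (0.63 ± 0.72, adjusted p = 0.75) did not pass. For P2ry12, pull-down with LPS was not above IgG1, which limits its term. Interferon-stimulated genes were lower in 4 of 30, or 9 adjusted over the list alone (adjusted camera p = 8.12e-05, adjusted p = 0.285 with an estimated correlation), and immediate early genes in 5 of 24, or 7 with 1 higher adjusted over the list alone (0.00857, adjusted p = 0.285 with an estimated correlation). Of 24 microglial genes 0 passed (0.979), with a median of 0.02 and a mean of -0.04. In all, 367 genes passed the edgeR test, 91 higher and 276 lower. The count fell to 196 without LPS sorted replicate 3. It was 211 to 229 without PBS sorted replicate 2, 1 or 3, 222 and 240 without PBS pull-down replicate 3 and 1, and 222 and 244 without LPS pull-down replicate 1 and 2.

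For pull-down from sorted cells against sorted cells, the interaction with LPS was called for 0 genes by edgeR, with 761 at an unadjusted p under 0.05, and for 4 genes by DESeq2. Without LPS sorted replicate 1 edgeR called 1, and without PBS sorted replicate 1 it called 2. P2ry12 stood at -0.28 ± 0.25 (adjusted p = 0.895) and Jun at 0.52 ± 0.22. Immediate early genes, with a median of 0.27, had an adjusted camera p = 0.00785 and an adjusted p = 0.375 with an estimated correlation, and microglial genes, with a median of -0.27, had 0.000972 and an adjusted p = 0.589 with an estimated correlation. No member of either list passed, adjusted over the list alone or over all genes. At this depth the self-test recovered 54 of 100 genes changed 4-fold.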

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

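The tests of cells left out by the gate, of the signal without tamoxifen (all 3) and of regrouped libraries were chosen after the results they measure were seen, and the other tests before.

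Genes at least 2-fold lower in sorted cells than in pull-down of the digest experiment numbered 3187. Of these, 76.3% lay lower in pull-down than in IgG1 in the LPS experiment, against 50.1% of all genes, so RNA of other cells carried along by the pull-down is a candidate explanation for much of the pattern. Ribosome association in place of cell origin was argued against, since the same genes stayed low in pull-down from sorted cells, with a median of -1.71 against whole-brain pull-down (quartiles -2.58 and -0.95). A smaller part, 16.8%, was called higher than IgG1 and may come from tagged cells outside the gate, as 10 of 11 border macrophage genes were lower in pull-down from sorted cells, with Pf4 at -6.41 ± 0.34 and Mrc1 at -2.85 ± 0.50. That gate keeps CD45 intermediate cells, and no test here separates cells lost in preparation from cells outside it.

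Pull-down without tamoxifen held microglial RNA. The microglial list had a median of 3.63 over IgG1, so carry-over at the level seen with IgG1 was argued against. IgG1 stood at -0.04 against input for this list, so that median largely followed from the 3.74 of pull-down over input. The stated amounts were 125 µg of anti-HA and 1 µg of IgG1. Carry-over that rises with the amount of antibody was thus not covered and stays open, as does recombination in microglia without tamoxifen, both untested. A set of 15 genes lay above IgG1, input and the tamoxifen pull-down, among them Ap2b1 (log2 6.67 over IgG1, against 0.48 for its partner subunit Ap2m1), Mmp9 (224 reads against 0 in IgG1, at least 306-fold higher), Mmp2 (389 against 1, a ratio of 1600, 95% interval 285 to 63200) and Atp10b (42 against 1, a ratio of 172, 29.3 to 6970). Binding of the antibody or beads to something other than tagged ribosomes stays open for these, as 60% were higher in pull-down than IgG1 and lower in sorted cells in the digest experiment, against 30.4% of the other 575 genes above IgG1 without tamoxifen, but so were 10 of 11 border macrophage genes, so this does not separate it from tagged cells outside the gate. Recombination in another listed cell type stays open for the set, since the 8 other cell type lists had a highest median over IgG1 of 0.64 (endothelial) but stood at a mean log2 CPM of 3.47 to 8.89 in IgG1, which would hide a small share.

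The response to LPS was called lower in sorted cells than in pull-down for 276 genes. Their median response was -1.45 in sorted cells and -0.07 in pull-down. A response of other cells in the background was argued against for the set as a whole, as the median in IgG1 was 0.05 (quartiles -0.13 and 0.27). Most of the set, 230 genes, was called lower with LPS in sorted cells. For the 58 called higher with LPS in pull-down, the IgG1 response was not measured apart, so this explanation stays open there. Dilution by RNA of other cells stays open. Genes lower with LPS in sorted cells and lower in pull-down than IgG1 had a median of -0.34 in pull-down, between the values either outcome needed. Those at least 2-fold higher than IgG1 had a median of -0.76 in pull-down, which met the other part of the prediction. In sorted cells the medians of these sets were -1.23 and -1.18. Activation during sorting stays open too, with a median of 0.22 for sorted cells against pull-down in the digest experiment (quartiles -0.47 and 1.26), where 126 genes were higher and 80 lower of 269. Over all genes that median was -0.17, with 3647 higher and 4744 lower of 11529.

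The driver and pull-down term differed for 5171 genes by its interaction test. Higher with the constitutive driver were Fut9 (7.75), Bicd1 (6.84), Triqk (6.75), Hrasls (6.43) and Tmem255a (6.27), all log2 and all with 0 reads in the tamoxifen pull-down, so these fitted values are no bounds. Lower were Itgax (-6.69), Runx1 (-6.66), Csf2rb2 (-6.59) and Cd163 (-6.12), of which Itgax and Csf2rb2 had 1 to 3 reads in at least 1 group and Itgax missed the threshold without input replicate 1 (adjusted p = 0.0561) or 2 (0.0528) of the constitutive driver. Among the fixed genes, Tmem119 (-4.04), P2ry12 (-3.13), Cx3cr1 (-3.83), Mrc1 (-3.48), Fos (1.82, with input lower for the constitutive driver) and Snap25 (2.78) passed. Mrc1 lost its call without any 1 of 5 libraries, with an adjusted p of 0.644 and a log2 value of -0.71 without input replicate 3.

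The interaction of LPS with preparation passed for 367 genes. The difference, as log2 change in sorted cells less that in pull-down, was above 0 for Noct (5.28), Ptgs2 (5.21), Dusp14 (5.01), N4bp3 (3.56) and Adamtsl4 (3.51). It was below 0 for Ypel2 (-7.26), Tmem252 (-7.26), Spred3 (-5.34), Myadml2 (-5.02) and Npdc1 (-4.63). Each of the 10 had 0 to 2 reads in a group of sorted cells, so these fitted values are no bounds either. Noct and Ypel2 passed with any single library left out. The highest adjusted p of the others was 0.505 for Ptgs2 (without PBS pull-down replicate 1), 0.147 for Dusp14, 0.171 for N4bp3, 0.0667 for Adamtsl4 and 0.0622 for Spred3 (each without PBS sorted replicate 1), 0.225 for Tmem252 (without PBS sorted replicate 2), and 0.14 for Myadml2 and 0.131 for Npdc1 (both without LPS sorted replicate 3).

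Comparisons outside the main ones, run with a library left out but not with the other alternatives, gave 965 genes called between pull-down and IgG1 without tamoxifen, 359 and 496 without pull-down replicate 1 and 2, and 4601 for the constitutive driver. In the latter, microglial genes were higher in 16 of 23, with a median of 1.63 (adjusted camera p = 1.89e-08, adjusted p = 0.484 with an estimated correlation). Neuronal genes were higher in 4 and lower in 6 of 23, with a median of -0.14 (0.638, adjusted p = 0.82 with an estimated correlation). As a list they were thus not above IgG1 with this driver.

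A library far from the others of its group was found for 10 of 94 values tested, where chance gives about 1 in 20. Among these, LPS IgG1 replicate 3 had reads in 13617 genes. It was also the shallowest of its group, at 610257 counts against 1025107 to 1129597 in the others. For 6 of the 10 the other libraries held 0 reads, so that any read was enough, and these say nothing of a library that stands apart. They were as follows. LPS pull-down from sorted cells replicate 1 held Mrc1 at 5.57 CPM, and IgG1 replicate 2 of the digest experiment held Tnf at 0.596 CPM, from 3 reads and 1. In cells sorted after the digest, Snap25 stood at 2.14 and Gfap at 1.07 CPM in replicate 1 and Cldn5 at 0.868 CPM in replicate 3. Without the digest, Snap25 stood at 0.844 CPM in replicate 4.

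Regrouping the libraries of a comparison gave 35 splits with 3 and 4 libraries. It was not run for pull-down without tamoxifen against input or against pull-down with tamoxifen. No other split called as many genes for LPS in pull-down (3037, highest other 1666), sorted cells (3949, other 3053) or pull-down from sorted cells (2933, other 2096). Nor did one for LPS in IgG1 (132, other 47) or the interaction with sorting (367, other 27). The same held in the digest experiment for pull-down against IgG1 (8594, other 5256), and for sorting with (8391, other 5382) and without the digest (8397, other 5108) against pull-down. It also held, between 4 and 4 libraries, for the digest (16, other 2). The real split was then 1 of 35, the smallest share that can be reached. These tests were chosen after the results were seen and were not adjusted over comparisons, so they do not exclude chance. For the interaction of LPS with pull-down from sorted cells the real split called 0 and the highest other 1, and since any split reaches 0 (35 of 35), the count decides nothing about chance. The other comparisons that were regrouped had 10 splits, too few for a share under 0.05. In PBS mice the highest other count was 0 for pull-down against IgG1 (7434), sorted cells (8226) and pull-down from sorted cells (6145) against pull-down, and 3 for pull-down from sorted cells against sorted cells (3645). In the driver experiment it was 0 for tamoxifen pull-down against input (7617) and IgG1 (7850), 10 for the constitutive driver against input (4138), and 0 between the drivers (6616) and their enrichments (5171).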

How the results depend on the processing

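Alternatives chosen after the data were seen were the ribosomal RNA gene Rn45s left out of the totals, pull-down from sorted cells without its 3 shallowest libraries, and the tamoxifen pull-down thinned to the depth without tamoxifen; the others were chosen before. Depth limits the pull-downs without tamoxifen and from sorted cells, where 3 reads over a library stood for up to 16.1 and 18 CPM. Counts of the 21 main comparisons stayed within 1.5 times of the reported ones with DESeq2 size factors in edgeR and with Rn45s left out, and those of the 15 that could be blocked with the replicate block. A minimum count of 50, which tests fewer genes, gave 5002 for tamoxifen pull-down against input and 5134 against IgG1, 5710 for pull-down against IgG1 in the digest experiment, 5443 and 5473 for sorting with and without digest against pull-down, 4928 for pull-down against IgG1 and 5043 for sorted cells against pull-down in PBS mice, 3 for the interaction of LPS with pull-down from sorted cells and 4065 for genes shared by both experiments. No filter on low counts gave 25 for the digest and 213 for LPS in IgG1. The DESeq2 Wald test gave 25 for the digest and 4 for the interaction with pull-down from sorted cells, which was 4 with total-count scaling and 2 without the 3 shallowest libraries. A fit on the groups of the contrast alone gave 30 for the digest, 84 for LPS in IgG1, 552 for the interaction with sorting and 5 for that with pull-down from sorted cells. An estimated correlation left 82 of 179 list tests called, against 217 with fry. Apart from the minimum count, the cause was not tested.

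With 1 library left out in turn, counts ran from 451 to 817 for pull-down without tamoxifen against input, 2517 to 4001 against pull-down with tamoxifen, 86 to 172 for LPS in IgG1, 196 to 437 for the interaction with sorting and 0 to 2 for that with pull-down from sorted cells. The count for LPS in IgG1 was 86 without LPS IgG1 replicate 2. Without pull-down replicate 1 of the constitutive driver, Gfap and Cldn5 reversed against the tamoxifen pull-down (-1.26 and -1.45) and in the enrichment (-1.54 and -1.61). None of these 4 was called with all libraries. Their highest values with another library left out were 0.77, 1.56, 0.49 and 1.40. Snap25 with LPS in pull-down from sorted cells was -1.41 without the 3 shallowest libraries, against 0.39 with all libraries, where it was not called. The cause was not tested. Counts of the other main comparisons stayed within 1.5 times, and the counts of shared genes were not run with a library left out. For named genes with a library left out, 11597 results kept direction and side of the threshold, 542 lost and 84 gained a call, and 4 reversed.

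Thinning gave 3131 genes for pull-down without against with tamoxifen. Scaling moved the median gene by more than 0.1 in several comparisons, from -0.53 to 0.46. Libraries with the same replicate number resembled each other little beyond their group. Their mean correlation was 0.03, 0.03 and 0.02 in the LPS, digest and driver experiments, against -0.01 in each for different numbers. Each library was centred on its group mean, so the value for different numbers follows from the other and is no separate reference. A library was closest to the one with its own number in 54.8%, 50% and 58.3% of cases, against 28.6%, 26.8% and 37.5% by chance. These shares lean toward a pairing by animal without settling it, and the main tests treated the libraries as unpaired. The block gave 24 genes for the digest and 439 for the interaction with sorting, and called 138 of 279 list tests against 134.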

Other observations

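Observations on IgG1 libraries and on sex-linked genes were chosen after the data were seen.

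IgG1 libraries were not a sample of the input. In the driver experiment, edgeR called 4148 genes between IgG1 and input with tamoxifen (1965 higher, 2183 lower), 2989 without tamoxifen (1804 to 2070 with 1 of the 4 libraries left out) and 3251 with the constitutive driver. Ddx3y, a Y-linked helicase, had 441 reads over the 3 IgG1 libraries and 39 over the 3 input libraries with tamoxifen. Other Y-linked genes differed far less, with 31 against 14 reads for Eif2s3y, 15 against 24 for Kdm5d and 12 against 10 for Uty. The large difference was thus one of Ddx3y and not of Y-linked RNA as a whole.

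The experiments behind the shared comparison of sorted cells with pull-down differed in sex-linked RNA. Sorted cells after the digest held 1115 reads of Xist, the noncoding RNA of the inactive X chromosome, over 4 libraries and 0 of Ddx3y, while sorted cells of PBS mice in the LPS experiment held 1 read of Xist and 430 of Ddx3y over 3 libraries. Xist also differed between preparations, as pull-down of the digest experiment held 5 reads over 3 libraries and IgG1 15 over 4. Ddx3y had 2 and 0 reads there, so Y-linked RNA was near absent in these preparations as in the sorted cells. The low Xist in them is thus no sign of mice of another sex.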
